A study of Mus musculus with 6 samples.

How the data were processed

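RNA was extracted from pelleted mouse oviductal cells with a Qiagen kit and sequenced on an Illumina HiSeq 2500 after a standard Illumina library preparation, per the labels' protocols and the series design text. The strand setting of the counting and the gene annotation are not given in the sources used here. Cutadapt, STAR, HTSeq and DESeq2 and the genome build mm10 are named in the submitters' processing notes, without versions or roles.

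The deposited values are 1 non-negative signal per gene symbol and library: read counts per gene divided by 1 factor for each library, of the kind DESeq2 gives. That the authors scaled counts in this way was read from the values. In each library, 100% of the values above 0 were whole multiples of 1 smallest step within a tolerance of 0.02 reads. The step ran from 0.841 to 1.10 normalized counts per read. Dividing by it recovered whole reads, which summed to 25.8 M, 27.3 M and 34.0 M in scramble replicates 1, 2 and 3 and to 28.9 M, 31.1 M and 27.0 M in PTEN shRNA replicates 1, 2 and 3. Totals of normalized counts ran from 27.2 M to 31.1 M. For scramble replicate 2 the step, 0.997, was so close to 1 that an automatic check could not tell it from 1, and its reads were recovered in the same way. Counting intervals and floors cover counting error only, since PCR copies could not be told apart. For Pten, the 2879 reads of scramble replicate 1 have an exact 95% binomial interval of 107 to 116 counts per M reads, and the 542 reads of PTEN shRNA replicate 1 one of 17.2 to 20.4.

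The files list 23337 gene symbols, of which 6670 were at 0 in all libraries. 1 gene lacked a value in 1 library and was left out. Genes that share reads with near-identical copies, such as Eno1 and Gapdh with their pseudogenes, may be undercounted. Rn45s, the precursor of ribosomal RNA, took 0.362% to 0.678% of reads in scramble and 0.569% to 1.40% in PTEN shRNA libraries, with PTEN shRNA replicate 2 the highest. Samples were grouped by the source name because it gives both group and replicate. The treatment field gives the other group for 2 of the 6 libraries. No 2 libraries of a group agreed within sampling noise: chi-square over its degrees of freedom was 27.4 or more in every pair of the same group.

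The planned test was edgeR's quasi-likelihood test with TMM scaling, on the assumption of raw counts. As the values proved to be normalized, the main test became limma 3.58.1 in R 4.3.3 with an intensity trend in the prior variance, on log2(normalized count + 1). Genes with a normalized count of at least 10 in at least 3 libraries were kept, 12299 in all, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The 30 gene lists, the grouping, the rule for named genes and the first set of other settings were fixed before the data were examined. Of the lists, 28 had at least 5 tested members. The leukocyte list had 3, and the mitochondrially encoded messenger RNAs were not among the symbols listed. In all 16 list genes were not found, 13 of them mitochondrial, and 10 were matched through an older symbol. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Members at 0 in 1 whole group were also set to the bound given by 3 reads per library, which moved the median of 0 lists.

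The rule for named genes takes Pten and the 7 largest rises and 7 largest falls among changed genes with at least 10 CPM in the higher group and no overlap between groups, passing over predicted and unnamed loci. It also takes the 3 members of smallest adjusted p of each list called by camera and 1 member of every other list, if past 0.05. This gave 46 genes. Further list members are named as examples, chosen after their values were seen. Positions are from the RefSeq annotation of GRCm38.p6, the assembly that mm10 corresponds to, matched by symbol or older symbol for 12218 of the tested genes (99.3%). GC content and length are from the longest GENCODE M21 transcript of each gene.

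These other settings were the treatment field as grouping, the 4 libraries whose label fields give the same group, DESeq2 1.42.0, limma-voom, edgeR 4.0.16 with RLE factors or library totals, glmTreat against 1.5-fold, no filter, a filter of 1 CPM, the replicate number as a block, and each library left out in turn. Count tests ran on recovered reads, and edgeR kept 12286 genes. The planned test, edgeR with TMM, was also run on the recovered reads (2963 genes called). Alternatives added after the data were seen were pseudocounts of 0.5 and 10 and TMM rescaling of the deposited values. Subtraction of a running median over 51 neighbouring genes was also added then. Plots were drawn with matplotlib.

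The fits were tested on simulated counts for the 12299 genes of the comparison of PTEN shRNA with scramble, with 50 genes changed at each of 4 fold sizes. Limma recovered 6%, 42%, 88% and 90% of the genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, and 9 of its 122 calls were unchanged genes. Camera called a shifted list of 25 genes in 20 of 20 draws and 2 of 540 unchanged lists. The simulated genes varied independently, while the correlation estimated for the real lists reached 0.995, for mitosis and G2/M. The simulation therefore says nothing on false calls among lists of correlated genes. The search for stretches of neighbouring genes, run on 10000 simulated genes, found both edges of an implanted stretch within 3 genes in 19 of 20 draws.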

Results

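RNA profiles of mouse oviductal cells were compared between cells carrying a short hairpin RNA against PTEN and cells carrying a scrambled control hairpin. A short hairpin RNA is processed in the cell into a small RNA that lowers the messenger RNA it matches. PTEN is the lipid phosphatase that opposes PI3K, and the series asks what its loss does in cells of the fallopian tube. The 6 libraries fell into 2 groups of 3, named scramble and PTEN shRNA. The files held 23337 gene symbols per library, with between 25.8 M and 34.0 M reads assigned to genes. Values are normalized read counts, and fold changes are differences of log2(normalized count + 1), which understate the change of weakly expressed genes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over 12299 genes unless another test is named. Nothing in the labels says that the replicates were separate cultures, so these p-values measure only the spread between the 6 samples, which may be technical.

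Pten was lower in every PTEN shRNA library. Its normalized count was 3179.5, 3440.7 and 3504.9 in scramble replicates 1 to 3 (mean 3375 ± 172, SD, n = 3). It was 582.7, 580.9 and 568.6 in PTEN shRNA replicates 1 to 3 (mean 577 ± 7.70, SD, n = 3). The remaining level was 0.171 of that in scramble cells, a log2 fold change of -2.54 with a standard error of 0.0838 (adjusted p = 8.77e-05). The gene lies on chromosome 19 between 32757577 and 32826160 (GRCm38, mm10). The labels carry 2 fields for the treatment, and these disagree for PTEN shRNA replicate 1 and scramble replicate 3. Groups were taken from the source name, and Pten follows that field in all 6 libraries. Grouped by the other field, the Pten difference was -0.82 (adjusted p = 0.867).

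**Figure D1:**
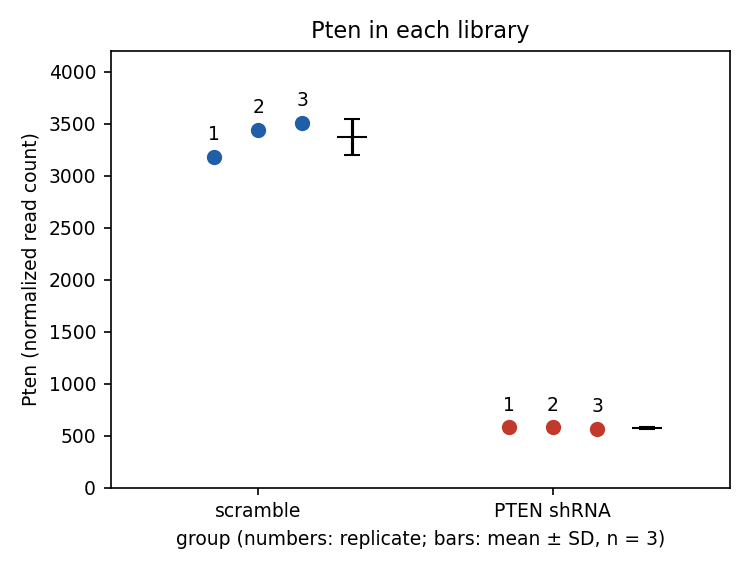
Normalized read count of Pten (vertical axis) in each of the 6 libraries, with the replicate number above each point and the mean ± SD of each group (n = 3) beside the points. The 3 PTEN shRNA libraries lie between 568.6 and 582.7, all below the scramble libraries, which lie between 3179.5 and 3504.9.

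Expression differed widely between the groups: 2968 of the 12299 tested genes changed, of which 1586 were higher and 1382 lower in PTEN shRNA cells. All 3 libraries of a group lay beyond all 3 of the other for 5342 genes (43.4%), where chance alone gives 10%. The first principal component, with 68.1% of the variance, separated the groups. The second, with 23.2%, placed PTEN shRNA replicates 1 and 2 farthest apart, at -57.9 and 42.7. The count of changed genes differed when single libraries were left out, which also leaves fewer samples. It was 4751 without PTEN shRNA replicate 1 and 1635 without PTEN shRNA replicate 3, and it was 1324, 1469 and 1135 without scramble replicates 1, 2 and 3. With the groups of the other label field no gene passed in limma, the tool run on that grouping, and 148 had an unadjusted p under 0.05. Against a minimum fold of 1.5, edgeR's glmTreat on recovered reads called 915 genes, 563 higher and 352 lower.

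The largest rises were in genes that were almost silent in scramble cells. Sgce, which encodes epsilon-sarcoglycan, and Peg10, a retrotransposon-derived gene expressed from the paternal allele, are neighbours on chromosome 6 and rose together. Sgce went from 1.03 ± 0.999 to 997 ± 225 (SD, n = 3) and Peg10 from 0.368 ± 0.638 to 386 ± 86.8 (SD, n = 3). Only 3 reads of Sgce and 1 read of Peg10 stood behind the scramble values, so the ratio has a 95% counting interval of 347 to 4919 for Sgce and of 218 to 48031 for Peg10. Svil, the actin-binding supervillin, reached 574 ± 297, Kif26b, a kinesin family member, 453 ± 241, and Plcg2, a phospholipase C of receptor signalling, 296 ± 49.0 (SD, n = 3). Efha1, a regulator of mitochondrial calcium uptake, reached 641 ± 9.73 (SD, n = 3). Each of these 4 genes had 1 read in the scramble libraries together. Khdrbs3, an RNA-binding protein gene, was listed at 0 in all 3 scramble libraries and at 295, 350 and 374 in the PTEN shRNA libraries. Log2 fold changes of these 7 genes ran from 7.84 for Plcg2 to 9.05 for Sgce, and the largest adjusted p was 0.000275, for Kif26b.

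The largest fall was in Mecom, a zinc finger transcription factor gene on chromosome 3, from 1494.5 to 4.43 (log2 fold change -8.12, SE 0.196, adjusted p = 5.99e-05). Il22ra1 and Il28ra, which encode receptor chains for interleukin 22 and for type III interferons, are neighbours on chromosome 4 and both fell, from 286 to 2.40 and from 332 to 22.8. Frat2, a GSK3-binding protein gene of the Wnt pathway, fell from 514 ± 89.0 to 9.76 ± 0.0848 (SD, n = 3). H19, an imprinted non-coding RNA, fell from 332 to 17.8, Slco4a1, an organic anion transporter, from 3113 to 154, and Mal, a membrane traffic protein of epithelial cells, from 1119 to 52.7. H19 had the largest adjusted p of these genes, 0.00755.

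Genes of the extracellular matrix moved both ways, with more higher than lower. Among 24 tested genes for collagens and matrix structure, 10 were higher and 1 lower over all genes, and 13 and 2 were so when adjusted over the list alone. The list was higher than other genes by camera with a preset correlation (median log2 fold change 0.87, adjusted p = 0.00342), and not with an estimated correlation (adjusted p = 0.76). By fry, which tests the list's genes without comparing them to other genes, it moved upwards (adjusted p = 0.00773). Loxl2, a collagen cross-linking enzyme, rose from 611 ± 51.7 to 3306 ± 357 (SD, n = 3; log2 fold change 2.43, SE 0.118, adjusted p = 0.000172). Col4a1, a basement membrane collagen, rose from 25.9 to 170, and Col5a1, a fibrillar collagen, from 1.31 to 27.7, the former value resting on 4 reads. Col18a1, also of the basement membrane, was the member that fell, from 42785 to 26958. Matrix proteases and their inhibitors had 8 members higher and 2 lower of 19 (9 and 2 adjusted over the list alone). Mmp23, a membrane-anchored metalloprotease, rose from 4.85 ± 0.785 to 260 ± 72.4 (SD, n = 3), and the inhibitors Timp1 and Timp3 rose by log2 1.16 and 1.67. Mmp11 and Plau were the 2 that fell.

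Adhesion and epithelial genes moved both ways. Of 25 integrin and focal adhesion genes, 4 were higher and 6 lower (4 and 7 adjusted over the list alone). Itgb6, an epithelial integrin chain, fell from 321 ± 25.8 to 31.0 ± 5.68 (SD, n = 3), Itga2 fell from 1535 to 466, and Itgb3 rose from 122 to 379. Of 22 genes for epithelial junctions and keratins, 6 were higher and 8 lower (6 and 9 adjusted over the list alone). Lama3, a laminin chain of epithelial basement membrane, fell from 240 to 19.8 (log2 fold change -3.54, SE 0.221, adjusted p = 0.000319). Cdh1, which encodes E-cadherin, fell by 1.55 on the log2 scale (adjusted p = 0.0312), while Cldn1, a tight junction claudin, rose from 4161 to 11441. Mesenchymal genes and factors of the epithelial-to-mesenchymal transition had 4 members higher and 2 lower of 20 (5 and 2 adjusted over the list alone). Cd44, the hyaluronan receptor, rose from 4811 ± 424 to 12202 ± 1927 (SD, n = 3). None of these lists, proteases included, stood apart from other genes by camera. Over the 26 lists that did not, adjusted p ran from 0.135 to 0.84. Median, mean and test differed in sign for ribosome biogenesis, epithelial junctions and keratins, integrins, secretory, smooth muscle and endothelial markers and TGF-beta targets.

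**Figure D2:**
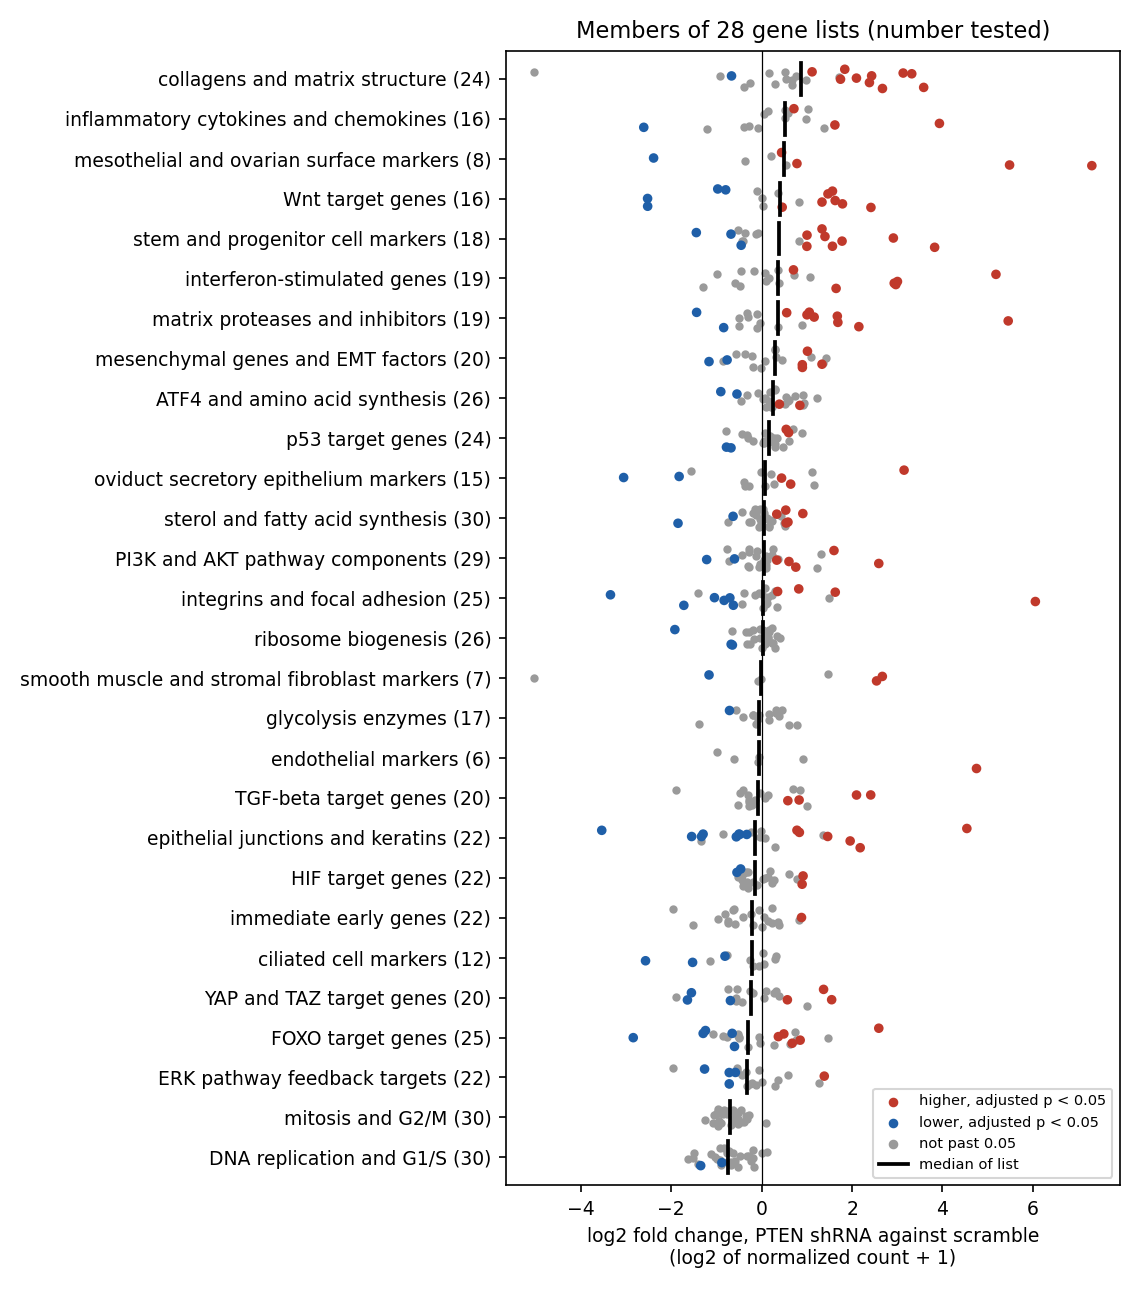
Log2 fold change (horizontal axis, PTEN shRNA against scramble, on the scale of log2 of the normalized count + 1) of each tested member of 28 gene lists, 1 list per line with the number tested in parentheses. Red points were higher and blue points lower at an adjusted p under 0.05, grey points did not pass, and the black bar is the list's median, which ran from -0.74 for DNA replication and G1/S to 0.87 for collagens and matrix structure.

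Markers of oviductal cell types did not move as sets. Of 15 secretory epithelium markers, 3 were higher and 2 lower (4 and 2 adjusted over the list alone). Pax2, a transcription factor of the Müllerian duct, fell from 13241 ± 703 to 3748 ± 420 (SD, n = 3; log2 fold change -1.83, SE 0.110, adjusted p = 0.000307). Pax8, its relative in secretory cells, was at 12224 in scramble and 12959 in PTEN shRNA cells (log2 fold change 0.07, adjusted p = 0.769). Of 12 ciliated cell markers, 3 were lower, over all genes and adjusted over the list alone, and the one of smallest adjusted p was Caps2, from 37.8 to 5.74. Stem and progenitor markers had 8 members higher and 3 lower of 18 (8 and 4 adjusted over the list alone). Kitl, the ligand of Kit, fell from 1492.5 to 548, and Kit itself rose from 37.9 to 641.

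Markers of other cell types were sparse. Of 20 leukocyte markers 3 passed the expression filter, too few for a set test. Cd68, a lysosomal protein of macrophages that other cells also make, rose from 191 to 349 (adjusted p = 0.0448; 1 higher and 1 lower adjusted over the list alone). Among the others, Ptprc, the common leukocyte antigen, had a mean of 3.12 in scramble and 1.32 in PTEN shRNA cells. Of 6 endothelial markers 1 was higher, over all genes and adjusted over the list alone: Kdr, a VEGF receptor, from 8.28 ± 1.44 to 271 ± 154 (SD, n = 3). Pecam1, an abundant endothelial gene, had means of 1.86 and 3.65. Of 8 mesothelial and ovarian surface markers, 4 were higher and 1 lower, over all genes and adjusted over the list alone. Igfbp5, an IGF-binding protein, rose from 3.36 ± 1.47 to 686 ± 229 and Podxl, a sialomucin, from 5.99 to 307, while Upk3b fell from 146 to 28.2. By fry, which tests whether a list's genes move on balance in 1 direction, this list was higher (adjusted p = 0.00306), and by camera it did not differ from other genes (adjusted p = 0.193). Of 7 smooth muscle and stromal fibroblast markers, 2 were higher and 1 lower (3 and 2 adjusted over the list alone), among them Cnn1, a calponin, from 20.4 to 135.

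Several named falls lay together on chromosome 19. Pax2, Frat2, Scd2, Aldh18a1 and Rrp12 lie between 38930262 and 45998632 (GRCm38), where 59 of 68 tested genes were lower, none was higher and 9 did not pass. This stretch was singled out after the values were seen. Its left edge is uncertain: the first gene, Hells, did not pass (log2 fold change -0.81, adjusted p = 0.39), and the next, Pdlim1, starts at 40.22 Mb. Plce1, outside the stretch at 38.48 Mb, was at -2.78. The median log2 fold change of the 58 more strongly expressed genes of the stretch was -1.57. Pten lies 6.1 Mb outside it, and the genes around Pten were on balance higher, not lower: the running median there was 0.52, against a median of -0.02 over all tested genes. Chromosome 10, which holds the named genes Erbb3, Hk1, Cdk4, Caps2 and Kitl, had a median of -0.39 over 533 genes. With the running median of neighbouring genes subtracted, an alternative chosen after the values were seen, the log2 fold changes of Scd2, Rrp12, Pax2, Hk1 and Cdk4 were -0.32, -0.67, -0.38, -0.40 and -0.37, and these genes no longer passed, while Frat2, Erbb3, Caps2 and Kitl passed at -4.32, -2.40, -2.19 and -0.93. Aldh18a1 was itself the median of its neighbours, so the subtraction left 0 by construction and tests nothing for it. E2f2 and Hspa1b also no longer passed (adjusted p = 0.0555 and 0.0683), with log2 fold changes of -1.28 and 0.80 against -1.35 and 0.87 before.

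**Figure D3:**
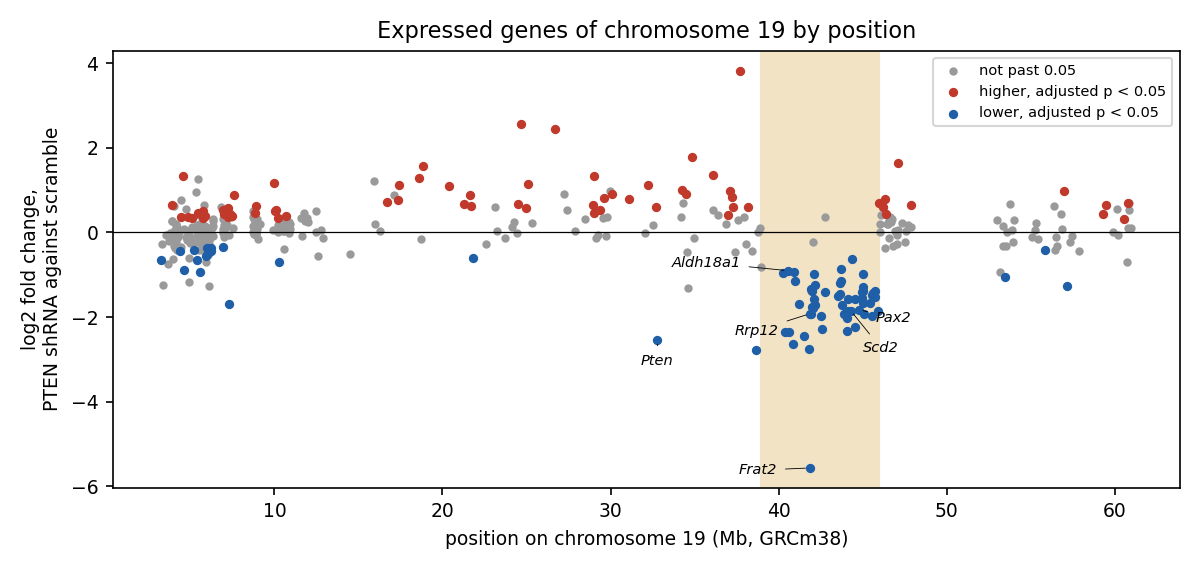
Log2 fold change (vertical axis, PTEN shRNA against scramble) of the 390 more strongly expressed genes of chromosome 19 against position in Mb (GRCm38). The shaded stretch from 38.93 to 46.0 Mb holds 58 genes with a median of -1.57, of which 54 were lower at an adjusted p under 0.05 (blue) and 0 higher (red).

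In the pathway that PTEN opposes, 5 of 29 PI3K and AKT pathway components were higher and 2 lower, over all genes and adjusted over the list alone. Over all 12299 tested genes 1586 were higher and 1382 lower, and the list did not differ from other genes by camera (median 0.04, adjusted p = 0.75). Its counts were 7 higher and 7 lower without PTEN shRNA replicate 1, and 3 higher and 4 lower with library totals. The insulin receptor substrates rose: Irs1 from 319 ± 18.6 to 973 ± 119 (SD, n = 3) and Irs2 from 24.8 to 157. Akt1 rose from 10079 to 15555, and Pik3cd and Rictor were the 2 that fell. Of 25 FOXO target genes, 5 were higher and 5 lower (5 and 6 adjusted over the list alone), but 5 and 12 without PTEN shRNA replicate 1 (median -0.62 against -0.31) and 3 and 8 in the 4 libraries whose labels agree. Erbb3, a receptor of the epidermal growth factor family, fell from 713 to 102 (log2 fold change -2.84, SE 0.253, adjusted p = 0.000989), the cell cycle inhibitor gene Cdkn1b fell from 2522 to 1603, and the catalase gene Cat rose from 8302 to 13353.

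The number of changed genes in metabolic lists depended on the setting. Of 17 glycolysis enzymes, Hk1, a hexokinase, was the 1 gene lower over all genes (10853 to 6776, adjusted p = 0.0496), and 0 were so adjusted over the list alone. Without PTEN shRNA replicate 1, 5 were higher and 2 lower. The Hk1 call was lost in several settings, including edgeR with TMM, the planned test (adjusted p = 0.0589). Eno1, an enolase gene of the same list, was listed at 0 in all 6 libraries, and Gapdh had means of 42.1 and 31.9, so both counts are uncertain. Of 30 sterol and fatty acid synthesis genes, 5 were higher and 2 lower, over all genes and adjusted over the list alone. The 2 that fell were the desaturase genes Scd2, from 202730 to 56593, and Scd1, from 24418 to 15961, both within the chromosome 19 stretch. The list had 2 higher and 4 lower with library totals, 5 and 4 without PTEN shRNA replicate 1, and 0 and 1 without scramble replicate 2. Of 26 ATF4 and amino acid synthesis genes, 2 were higher and 2 lower, over all genes and adjusted over the list alone, and 9 were higher and 2 lower with DESeq2. Aldh18a1, for proline synthesis, fell from 4720 to 2542 and Psph, for serine synthesis, rose from 504 to 912. This list was higher by camera at the preset correlation without PTEN shRNA replicate 3 (median 0.39, adjusted p = 0.0294) and not with all 6 libraries (median 0.26, adjusted p = 0.193, or 0.891 at its estimated correlation of 0.221). Of 26 ribosome biogenesis genes, 3 were lower, and 1 adjusted over the list alone: Rrp12 fell from 5222 to 1425. Without PTEN shRNA replicate 1, 5 of these genes were higher and 3 lower. Of 22 HIF target genes, 2 were higher and 2 lower (2 and 1 adjusted over the list alone), among them Adm, for adrenomedullin, from 618 to 1178.

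Genes of the cell cycle differed more between the PTEN shRNA libraries than between the groups. The DNA replication and G1/S list was lower than other genes by camera (30 genes, median log2 fold change -0.74, adjusted p = 0.0301), with 0 members higher and 2 lower, and 0 adjusted over the list alone. The call was lost on the TMM scaling of the planned edgeR fit (camera adjusted p = 0.0537) and with an estimated correlation (adjusted p = 0.891). It was also lost without PTEN shRNA replicate 1, where the median was -0.11 (adjusted p = 0.444) and 2 members were higher and 6 lower. Without scramble replicate 2 it was -0.67 and did not pass either (adjusted p = 0.0592). E2f2, an E2F transcription factor gene, fell from 246 to 104 and the kinase gene Cdk4 from 29844 to 16692. Of 30 mitosis and G2/M genes 0 passed, over all genes or adjusted over the list alone (median -0.70, camera adjusted p = 0.363), and with DESeq2 or edgeR on recovered reads the median lay between -0.04 and -0.01. Without PTEN shRNA replicate 1 this list was higher, with 10 members higher, a median of 0.51 and an adjusted p of 0.00273, and without PTEN shRNA replicate 2 it was lower, with a median of -1.48 and an adjusted p of 0.0129. Both calls are at the preset correlation, while the correlation estimated for this list over all 6 libraries was 0.995 (adjusted p = 0.891). Over the 60 genes of both lists, the median log2 ratio to the scramble mean was -2.94, 0.58 and -0.02 in PTEN shRNA replicates 1, 2 and 3. It was -0.15, 0.19 and -0.06 in the scramble libraries. Mki67, the proliferation marker, was at 425 in PTEN shRNA replicate 1 and at 4997 and 4407 in replicates 2 and 3, against 3238, 2987 and 3599 in scramble cells. Of 24 p53 target genes, 2 were higher and 2 lower, over all genes and adjusted over the list alone, among them Ddb2, a DNA repair gene, from 292 to 182.

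**Figure D4:**
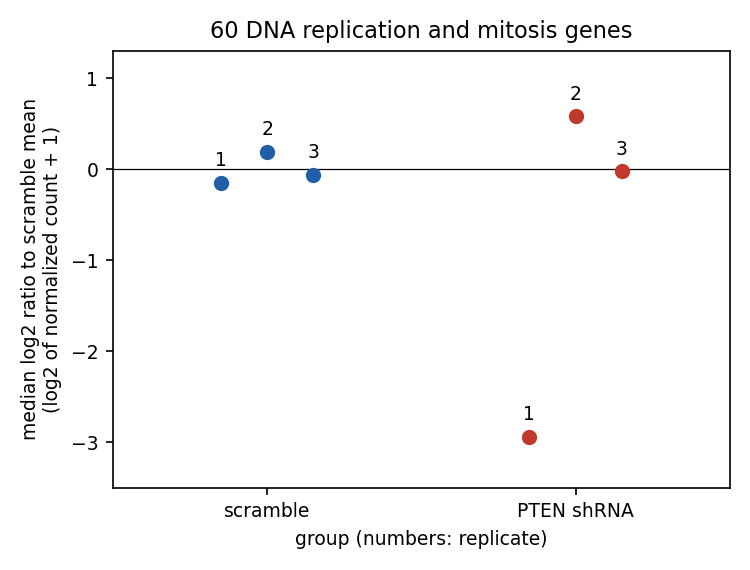
Median log2 ratio to the scramble mean (vertical axis, log2 of the normalized count + 1) over 60 DNA replication and mitosis genes in each library, with the replicate number above each point. PTEN shRNA replicate 1 lies at -2.94, and the other 5 libraries lie between -0.15 and 0.58.

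Interferon-stimulated genes had 6 members higher and 0 lower of 19 (7 and 1 adjusted over the list alone). Psmb8, a subunit of the immunoproteasome, rose from 8.67 ± 2.18 to 356 ± 110 (SD, n = 3; log2 fold change 5.18, SE 0.311, adjusted p = 0.000307), Xaf1 from 20.9 to 173 and Parp14 from 71.5 to 561. The list moved on balance upwards by fry (adjusted p = 0.0239) and did not differ from other genes by camera (adjusted p = 0.135), although Stat1 was at 1058 and 1356 (adjusted p = 0.132). Of 16 inflammatory cytokine and chemokine genes, 3 were higher and 1 lower, over all genes and adjusted over the list alone. Il1a, for interleukin 1 alpha, was listed at 0 in all 3 scramble libraries and at 19.4, 12.5 and 11.9 in the PTEN shRNA libraries, and the chemokine gene Cxcl5 fell from 310 to 52.7.

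Targets of other signalling pathways moved in both directions. Of 16 Wnt target genes, 7 were higher and 4 lower, over all genes and adjusted over the list alone. Axin2, a feedback inhibitor of the pathway, rose from 190 to 650, and Rnf43, a ubiquitin ligase that removes Wnt receptors, fell from 384 ± 38.4 to 67.9 ± 19.9 (SD, n = 3). Of 20 TGF-beta target genes, 4 were higher and 0 lower, over all genes and adjusted over the list alone, but 5 and 4 without PTEN shRNA replicate 1 and 3 and 3 in the 4 libraries whose labels agree. The activin antagonist gene Fst rose from 996 ± 52.6 to 4274 ± 378 (SD, n = 3). Of 20 YAP and TAZ target genes, 3 were higher and 3 lower (3 and 5 adjusted over the list alone). Asap1, an ARF GTPase-activating protein, fell from 2386 to 825 and Ankrd1 rose from 7959 to 19963. Of 22 ERK pathway feedback targets, 1 was higher and 4 lower, over all genes and adjusted over the list alone. These counts were 0 and 0 without scramble replicate 1, and 2 and 6 without PTEN shRNA replicate 1. The ERK inhibitors Spred1, Spred2 and Spred3 fell by 0.72, 0.72 and 0.58 on the log2 scale. Of 22 immediate early genes, 1 was higher, and 0 adjusted over the list alone: Hspa1b, from 84.8 to 156, a heat shock gene with a near-identical copy whose reads could be split between them. This list had 2 higher and 4 lower without PTEN shRNA replicate 1. It had 0 higher and 3 lower of 21 in the 4 libraries whose labels agree.

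Some named genes with adjusted p close to the threshold lost their calls when a library was left out, which also leaves fewer samples. Each of Hk1, E2f2, Cdk4, Ddb2, Cd68 and Hspa1b no longer passed when scramble replicate 1, 2 or 3 was left out, and Spred1 when scramble replicate 1 or 3 was. Without PTEN shRNA replicate 3 this held for E2f2, Cdk4, Cd68, Hspa1b and Spred1, and without PTEN shRNA replicate 2 for Hk1 and Hspa1b. Adjusted p in these fits ran from 0.0588 for Spred1 to 0.151 for Hk1. Without scramble replicate 1, 2 or 3 the log2 fold change of Hk1 was -0.74, -0.71 and -0.71, against -0.72 with all libraries, and that of E2f2 was -1.36, -1.36 and -1.33, against -1.35. Counts of list members moved as well. Without PTEN shRNA replicate 1 they were 8 higher and 3 lower for p53 targets, 3 and 6 for HIF targets, 4 and 8 for YAP and TAZ targets, 8 and 7 for stem and progenitor markers, and 7 and 11 for epithelial junctions and keratins. The epithelial list had fewer lower calls without scramble replicate 1 (5 higher, 1 lower) and without scramble replicate 2 (5 higher, 4 lower). Its median did not turn there: it was -0.25 and -0.14, against -0.14 with all libraries.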

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

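The fits with the running median subtracted, with TMM rescaling and with other pseudocounts were chosen after seeing the data. The fit with TMM in edgeR was the planned test, run on recovered reads. Pten kept its direction and passed under each alternative run on it except the treatment-field grouping, with log2 fold changes from -3.06 to -2.52. Under the treatment field 0 genes passed in limma (0 higher, 0 lower, 148 at an unadjusted p under 0.05), Pten was at -0.82, 8 lists passed, the DNA replication and G1/S median turned to 0.54, and Hk1, E2f2 and Cdk4 turned to 0.063, 0.13 and 0.035. That grouping puts 1 library of each source-name group into the other. The 2968 genes became 915 (563 higher, 352 lower) with glmTreat, whose construction asks for a minimum fold and which was run for gene counts only. The lower calls became 829 with the running median subtracted, which removes shifts shared by neighbouring genes, and 89 of the 2968 genes then had the opposite direction. The remaining tests, filters and scalings run on all 6 libraries gave 2741 to 3960 genes, and 0 of the genes called in the main test had the opposite direction there. Leaving out 1 library gave 1135 to 4751 genes, 690 to 2400 higher and 445 to 2351 lower. It was 4751 without PTEN shRNA replicate 1, 1635 without PTEN shRNA replicate 3, and 1324, 1469 and 1135 without scramble replicates 1, 2 and 3. Fewer samples also leave less power.

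Collagens and matrix structure passed by camera in every setting with the preset correlation. These include the treatment field (median 0.66, adjusted p = 0.0102), where 0 genes passed, so such a pass does not by itself show a difference between the groups. Its median of 0.87 did not pass with an estimated correlation (adjusted p = 0.76, when 0 lists passed), and passed with fry (adjusted p = 0.00773). DNA replication and G1/S, also the list lost with voom, library totals, TMM and TMM rescaling (1 list each), had medians of -0.75, -0.50, -0.47 and -0.77 there. Medians under edgeR are of its own fold changes and not of the log values that camera tested. With RLE factors the list passed at a median of -0.46 (adjusted p = 0.0295). It did not pass in the 4 libraries with agreeing labels (-0.19), with an estimated correlation or with fry (both -0.74). Leaving out 1 library gave 1 to 3 lists and medians for this list from -1.12 to -0.11. It was -0.11 without PTEN shRNA replicate 1 and -0.67 without scramble replicate 2, and passed in neither. Interferon-stimulated genes passed in addition with no filter, with the filter of 1 CPM and in the 4 libraries, where mitosis and G2/M passed upwards (median 0.48, adjusted p = 0.00201) against a median of -0.70 in all 6. Why the replication list did not pass with the other scalings was not tested. Of the other 45 named genes, 37 (with the running median subtracted, which leaves Aldh18a1 at 0 by construction) to 45 passed in each setting except the treatment field and glmTreat, and Il1a and Col5a1 were not tested with the filter of 1 CPM.

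Same-numbered replicates deviated together for numbers 1 and 2 (correlations 0.53 and 0.55) but hardly for 3 (0.06). Among libraries of the other group, PTEN shRNA replicate 3 correlated best with scramble replicate 2 (0.22). Scramble replicate 3 correlated best with PTEN shRNA replicate 3. Whether same-numbered samples were handled together stays open, and the main fit took no account of the number. The fit with the replicate number as a block called 3626 genes, 1886 higher and 1740 lower. Depth limits the weakest genes: the largest rises rest on 0 to 3 scramble reads per gene.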

Other observations

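Of the tests below, the splits of the samples, the shuffles of gene order and the 3 tests of the cell cycle genes were chosen only after the result was seen, and so were the genes named in the next 2 paragraphs.

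Imprinted genes were not among the lists fixed in advance, were not counted or tested as a set, and some are given here as single genes. Besides Sgce, Peg10 and H19, Usp29 fell from 177 to 73.8 and Grb10 from 4913 to 2879 (adjusted p = 0.0123 and 0.0186), while Peg13 rose from 621 to 1184 and Impact from 1946 to 2663 (adjusted p = 0.0444 and 0.0249). Peg3, next to Usp29 on chromosome 7, was at 12299 and 9161 and did not pass (adjusted p = 0.276).

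The same holds for these genes of growth factor receptors and developmental regulators. Fgfr4 rose from 3.78 to 373 and the ephrin receptor gene Ephb6 from 323 to 2505. The receptor kinase genes Pdgfra, Kit and Kdr are neighbours on chromosome 5, and Kit and Kdr rose while Pdgfra fell from 164 to 70.7. Wnt4, a signal of the female reproductive tract, rose from 1728 to 9833, the transcription factor genes Sox8 from 15.6 to 419 and Meis1 from 295 to 1352. Foxd1 fell from 1504 to 473 and Hoxb3 from 1964 to 806.

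The real split of the 6 libraries gave 2968 genes, 1 of 10 splits with as many, and the highest of the other splits gave 0. The 10 splits are too few for a share under 0.05.

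A first hypothesis concerns the chromosome 19 stretch from 38.93 to 46.0 Mb. Expression there may be lower because the PTEN shRNA cells carry fewer copies of it than the scramble cells. A permutation test argued against chance order of genes, as 0 of 1000 shuffles gave a stretch as large (p = 0.001, the smallest they can give), and matched gene sets argued against GC content, transcript length and expression level, as the lowest of their medians was -0.21 against -1.57. A single library is argued against as well, since the highest median among the 3 PTEN shRNA libraries was -1.56. In 19 weakly expressed genes of the stretch that were not used to find it, the pooled log2 ratio was -1.74, the direction that fewer copies would give. Whether the size of the fall matches any number of copies was not tested. The 58 more strongly expressed genes ranged widely, from -5.57 for Frat2 to 0.36 for Pyroxd2. Silencing of the whole stretch would lower the weak genes too, and no DNA was measured. The values are ratios between the groups, so they cannot tell whether the PTEN shRNA or the scramble cells changed. Whether such a change came with the loss of Pten or arose separately in either group of cells stays open, because it goes with the groups.

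A second hypothesis is that the 2 cell populations may differ in copies of larger parts of chromosomes. Medians were -0.39 on chromosome 10, -0.32 on chromosome 6 (-0.52 from 83.03 to 149.2 Mb), 0.36 on chromosome 12 and 0.25 on chromosome X, and chromosomes 10 and 6 held 13.8% and 11.5% of the lower calls but 5.08% and 4.8% of the genes tested. GC content, length and expression level are argued against, as each median kept at least 94.6% of its size after a fit on these, and so is a single library, as a median turned sign in 0 of the 3 PTEN shRNA libraries. Weak genes not used to find the shifts had medians of the same sign on 4 of the 4 chromosomes, but medians as large occurred on chromosomes 14 (0.39) and 18 (-0.32), whose other genes had medians of 0.03 and -0.01, so this is little support for copy number. Other stretches were shifted too, with medians of -0.48 on chromosome 13 (13.59 to 51.85 Mb) and -0.38 on chromosome 7 (18.89 to 30.66 Mb). On these and on chromosomes 10, 6, 12, X, 17 and 8, 0 of 1000 shuffles gave a stretch as large, as on chromosome 19. The explanations above were weighed for chromosomes 10, 6, 12 and X only. Regulation across whole chromosomes was not tested and stays open.

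A further hypothesis concerns the lower DNA replication and mitosis genes, which may reflect the growth state of 1 library and not the loss of Pten. Without PTEN shRNA replicate 1 the median of the 60 genes moved from -0.73 to 0.28, although 6 of the 30 replication genes were then called lower. Over the 3 PTEN shRNA libraries it spanned 3.52, against a difference of 0.79 between the group means. Only 1 of the 3 PTEN shRNA libraries lay below every scramble library, so a fall of the 60 genes as a set was not shared by all 3. This rule was set after the values were known, so it cannot decide whether the knockdown slowed the cell cycle. The median also pools 2 lists that parted without PTEN shRNA replicate 1 (-0.11 for replication, 0.51 for mitosis). Why PTEN shRNA replicate 1 differs, for example by cell density at harvest, stays open, as the labels give no such detail.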
